A study of Mus musculus with 16 samples.

How the data were processed

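Liver RNA of 16 WSB/EiJ mice was measured, 1 mouse per array, in 4 groups of 4: control females, tamoxifen-fed females, control males and tamoxifen-fed males. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, total RNA was extracted with a column kit, and Cy3-labelled cRNA was made from it and hybridised. Per the file headers, the arrays are a 1-colour Agilent design with 62976 spots, named for the mouse genome build mm9, and the images were read with Feature Extraction; the submitters' processing notes name version 10.7. The deposited scanner files hold, per the file headers, a processed signal per spot, which is an intensity on a linear scale, not scaled between arrays. A deposited value table holds the authors' intensity values of the same arrays. Set against the scanner files it was the processed signal times 1 factor per array, 2.81 to 4.67, with the 75th percentile over spots near 1000 on each array and column medians from 44.2 to 60.1; it is linear and not centred, and no part of its scale stayed unknown.

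Control spots and spots marked as outliers by the scanner software were left out, 122 to 193 outlier spots per array. The main values were log2 of the processed signal minus the array's 75th percentile over 59305 non-control spots, and spots of 1 probe were averaged. Of 55681 probes, 26762 were matched through their transcript accession to 1 gene symbol in a RefSeq table of the assembly GRCm38.p6, used for names and not for coordinates, and 28919 were unmatched and stayed without a symbol. Probes were kept when well above background on all 4 arrays of at least 1 group, which left 28386 probes, 17823 of them named. Each of 13818 genes was represented by its probe with the highest mean, and 10431 of them had 1 kept probe. Where a called gene had other kept probes, 722 of 817 had the same sign in females and 1090 of 1228 in males, and 3 and 29 were called in the opposite direction. The probes were designed on the reference strain, so sequence variants of WSB/EiJ can lower a probe's signal alike in all groups.

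A single limma model with a mean per group was fitted to the 16 arrays (R 4.3.3, limma 3.58.1 and the data.table package 1.17.8; 12 residual degrees of freedom, 2.54 prior degrees of freedom). The contrasts were tamoxifen against control in females, the same in males, the difference of these, and females against males on the control diet. P-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05, and all limma tests were two-sided. A gene not well above background on any array of a group has a bound there. Its fold is given as "at least", from the brighter group's mean against, per array of the dimmer group, the higher of the lowest signal among probes above background and the probe's own signal.

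The design, the alternatives, the naming rule and 36 gene lists were set before the data were examined. The lists held 852 entries, of which 851 resolved to a symbol and 757 were tested. They cover drug metabolism (CAR and PXR, AhR, NRF2, phase II), lipid, bile acid, glucose and one-carbon metabolism, DNA damage, repair and chromatin, cell cycle, acute phase, interferon and ER stress responses, hormone signalling and sex-biased genes, the circadian clock, fetal and preneoplastic markers, hepatocyte zones, 10 other cell types and sex chromosome transcripts. Each was tested with camera at its preset correlation of 0.01, with adjustment over the lists, in females, in males and for their difference, 108 tests in all. Every list p given with an estimated correlation comes from camera without the preset; for each of the 25 calls it was the highest adjusted p over the 6 alternatives, so all calls except the female-biased list in males and for the difference are lost there. Genes were named by rule: the 8 largest increases and decreases per sex among called genes with no overlap between groups, called members of each list by size of change, a fixed set of 9 genes, the 5 largest each way for the sex comparisons, and sex chromosome transcripts. The text takes from the list part the first 2 members of lists called in that sex and the first member of others. Some genes that the rule names are not reported here.

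Because each slide held 2 mice of each group, fold changes and list medians with the slide as a block equal those without it, apart from genes with one of 18 missing values. Slides were also tested alone, with 2 mice per group. The same replicate numbers in each group mark no pairing in the labels; the fit with them as a block is an alternative. Other alternatives were normexp background correction with an offset of 50, quantile normalization, the array median in place of the 75th percentile, the authors' deposited table, other filters on dim probes, outlier spots kept, other rules for several probes of a gene, only the groups compared, trended and robust or array-weighted fits, stricter thresholds, each mouse left out in turn, and for lists an estimated correlation and fry. Normexp had been planned on the mean signal; the scanner files hold no such column, so the median signal and the median background were used.

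The steps were tested on simulated data with 200 of 13818 genes changed. The simulated genes varied independently of one another, so the list result does not cover lists whose genes vary together. At a log2 change of 1, 86.6% were recovered for the female contrast, 80.6% for the male, 65.7% for the difference and 85.1% for the sexes on the control diet, and at 0.5 the shares were 32.8%, 46.3%, 11.9% and 32.8%. Of the calls, 4.03%, 5.16%, 4.27% and 6.58% were genes left as they were. In the list test 3 of 3 shifted lists were called and 0 of the others, and genes simulated with the same sex difference on both diets had medians in the slide split of 1.49 on the control diet and 1.51 on tamoxifen when chosen on slide 1, and of 1.495 and 1.493 when chosen on slide 2.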

Results

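Liver RNA of 16 mice of the WSB/EiJ strain, a wild-derived inbred strain, was profiled on 1-colour microarrays. The mice fell into 4 groups of 4: females and males on a control diet, and females and males on the same diet with 420 ppm tamoxifen, an oestrogen receptor modulator, for 12 weeks. The mice were 18 weeks old. The design text names gene expression and DNA adducts of tamoxifen in the liver as the subject, and the title adds genotoxic and epigenetic effects; adducts were not analysed here. The 75th percentile of the signal lay between 248 and 408 units per array, and between 248 and 292 on the male control arrays. From 48.5 to 55.8% of the probes on an array were well above background, and no spot was saturated. Each slide carried 2 mice of each group, and the number of arrays limits the precision. Arrays of the same group differed by a median of 0.137 to 0.257 log2 units, and no pair looked like a repeated measurement. Below, a change is a log2 difference with its standard error from limma over 13818 genes, with n = 4 mice per group and Benjamini-Hochberg adjustment.

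The control groups lay apart from the other arrays on the first 2 principal components, which held 46.0% and 19.1% of the variance. Male controls lay apart on the first (60.1 to 75.6) and female controls on the second (41.8 to 46.7). The tamoxifen-fed mice of both sexes overlapped, from -33.6 to -19.8 on the first component and from -22.6 to -12.5 on the second. They separated on the third component, with 7.53% of the variance, where treated females lay at -24.1 to -5.54 and treated males at 7.28 to 27.4. The median correlation between arrays, across genes, was 0.965 between female and male controls and 0.988 between tamoxifen-fed females and males. Within groups it was 0.989 to 0.993.

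**Figure D1:**
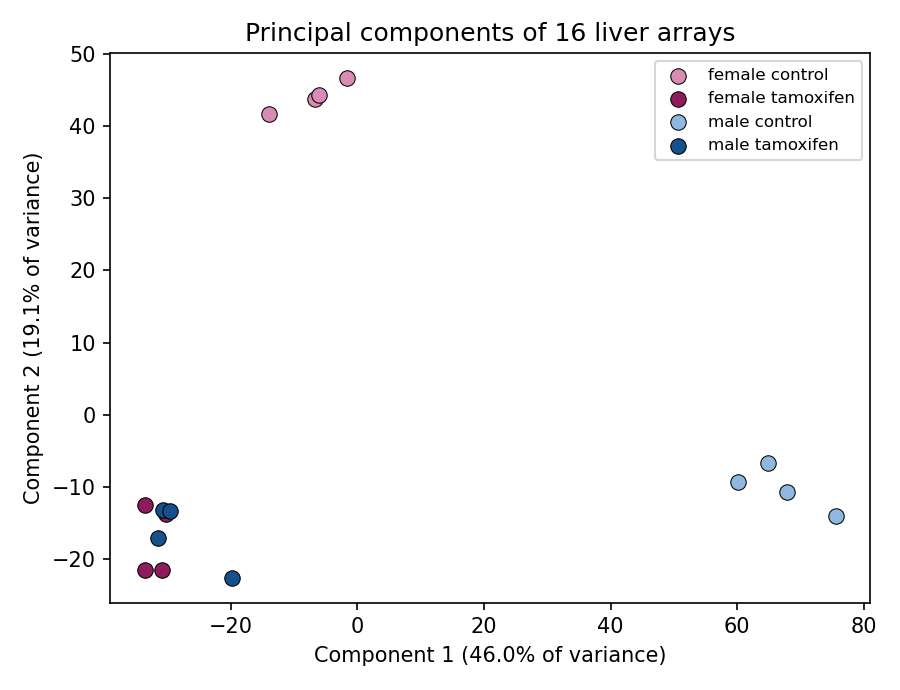
Position of each of the 16 arrays on the first and second principal components of the log2 values of the genes tested, with 1 point per mouse, coloured by group. The tamoxifen-fed females and males share 1 region of the plot, between -33.6 and -19.8 on the first component, while the control groups lie apart; the third component, not drawn, separates the treated sexes.

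The comparison of tamoxifen-fed with control females asked which liver transcripts changed with the diet in this sex. Large increases were in transcripts that were not well above background on any female control array: Kcnt1, a sodium-activated potassium channel, was at least 489-fold higher (adjusted p = 1.4e-09), Obp2a, an odorant-binding protein, at least 401-fold (adjusted p = 6.0e-11), and Syn2, a synaptic vesicle protein, at least 181-fold (adjusted p = 6.2e-09). Igfbpl1 was at least 18.3-fold and Sohlh1, a transcription factor of germ cells, at least 15.4-fold higher. Sfrp5, a secreted Wnt inhibitor (7.08 ± 0.70), Tuba8, an alpha-tubulin (6.07 ± 0.44), and Hrob, a recombination factor (5.78 ± 0.32), also rose. The largest fall was that of A1bg, a plasma protein, with a log2 change of -11.79 ± 0.51 (adjusted p = 1.4e-09). Prom1 (-5.40 ± 0.34), the lipase inhibitor G0s2 (-4.90 ± 0.36), Hsd3b1 (-4.74 ± 0.97), the peroxisomal oxidase Hao2 (-4.73 ± 0.65) and Nuggc (-4.47 ± 0.84) fell too. In all, 1336 genes rose and 1675 fell, of which 335 and 303 changed at least 2-fold. On slide 1 alone 420 genes passed and on slide 2 alone 1140, each with 2 mice per group; with the slide as a block 3085 passed and with the array median 1618. With quantile normalization more genes rose (1678) than fell (1615).

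Cholesterol synthesis had the lowest list median among the lists called in females. Of its 25 measured members 18 fell and 0 rose (21 and 0 adjusted over the list alone), with a median of -1.11, and -1.21 and -1.08 on slides 1 and 2 (camera adjusted p = 3.0e-10). Sqle, squalene epoxidase, fell by 4.10 ± 0.71 on the log2 scale. Of 28 genes of fatty acid and triglyceride synthesis 11 fell and 1 rose (12 and 3 adjusted over the list alone), with a median of -0.35, and -0.61 and -0.13 on the slides (adjusted p = 0.010); Acacb, an acetyl-CoA carboxylase, changed by -2.11 ± 0.37 and Pklr, liver pyruvate kinase, by -1.73 ± 0.21. Of 27 interferon response genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.52, and -0.72 and -0.34 on the slides (adjusted p = 2.1e-05). It was led by Cxcl10 (-2.25 ± 0.22) and Ifit1 (-1.83 ± 0.19). Adjusted p = 0.79 with an estimated correlation for each of these 3 lists. The numbers of the 35 splits of the 8 female arrays that gave as small a p were 5, 14 and 6. Each other split mixes the groups compared, so here and below such counts set no level expected by chance.

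Genes known to be higher in female liver fell in treated females: 14 of 23 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.88, and -0.92 and -0.99 on slides 1 and 2 (camera adjusted p = 3.3e-08, adjusted p = 0.25 with an estimated correlation, 1 of 35 splits). A1bg, Prom1 and Hao2 were among the genes that fell. Of 25 genes known to be higher in male liver 3 rose and 4 fell (3 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.83, median 0.15, mean -0.01). Hsd3b5, a male-biased steroid dehydrogenase, fell by 3.95 ± 1.14 (adjusted p = 0.022), which did not pass without female control 1 or 2 or female tamoxifen 3 or 4 (adjusted p = 0.057 to 0.061). Among markers of liver zones and cell types, 5 of 15 pericentral hepatocyte genes fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.43, and -0.43 and -0.42 on the slides (adjusted p = 0.032, adjusted p = 0.79 with an estimated correlation, 8 of 35 splits). Glutamine synthetase Glul (-1.93 ± 0.18) and the ammonium transporter Rhbg (-1.23 ± 0.21) led this list, whose call was lost with quantile normalization (adjusted p = 0.0504) and normexp (0.074). Of 19 endothelial genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.35, and 0.21 and 0.49 on the slides (adjusted p = 0.00091, adjusted p = 0.79 with an estimated correlation, 12 of 35 splits). Gpr182 (0.71 ± 0.12) and Kdr (0.61 ± 0.11) were its largest changes, and a second Kdr probe gave -0.12 (adjusted p = 0.53). With normexp, where the probe with the highest mean was chosen anew, Kdr gave -0.0899 and was not called (adjusted p = 0.687). That value may come from the second probe, so it is not shown to be an effect of the background correction.

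**Figure D2:**
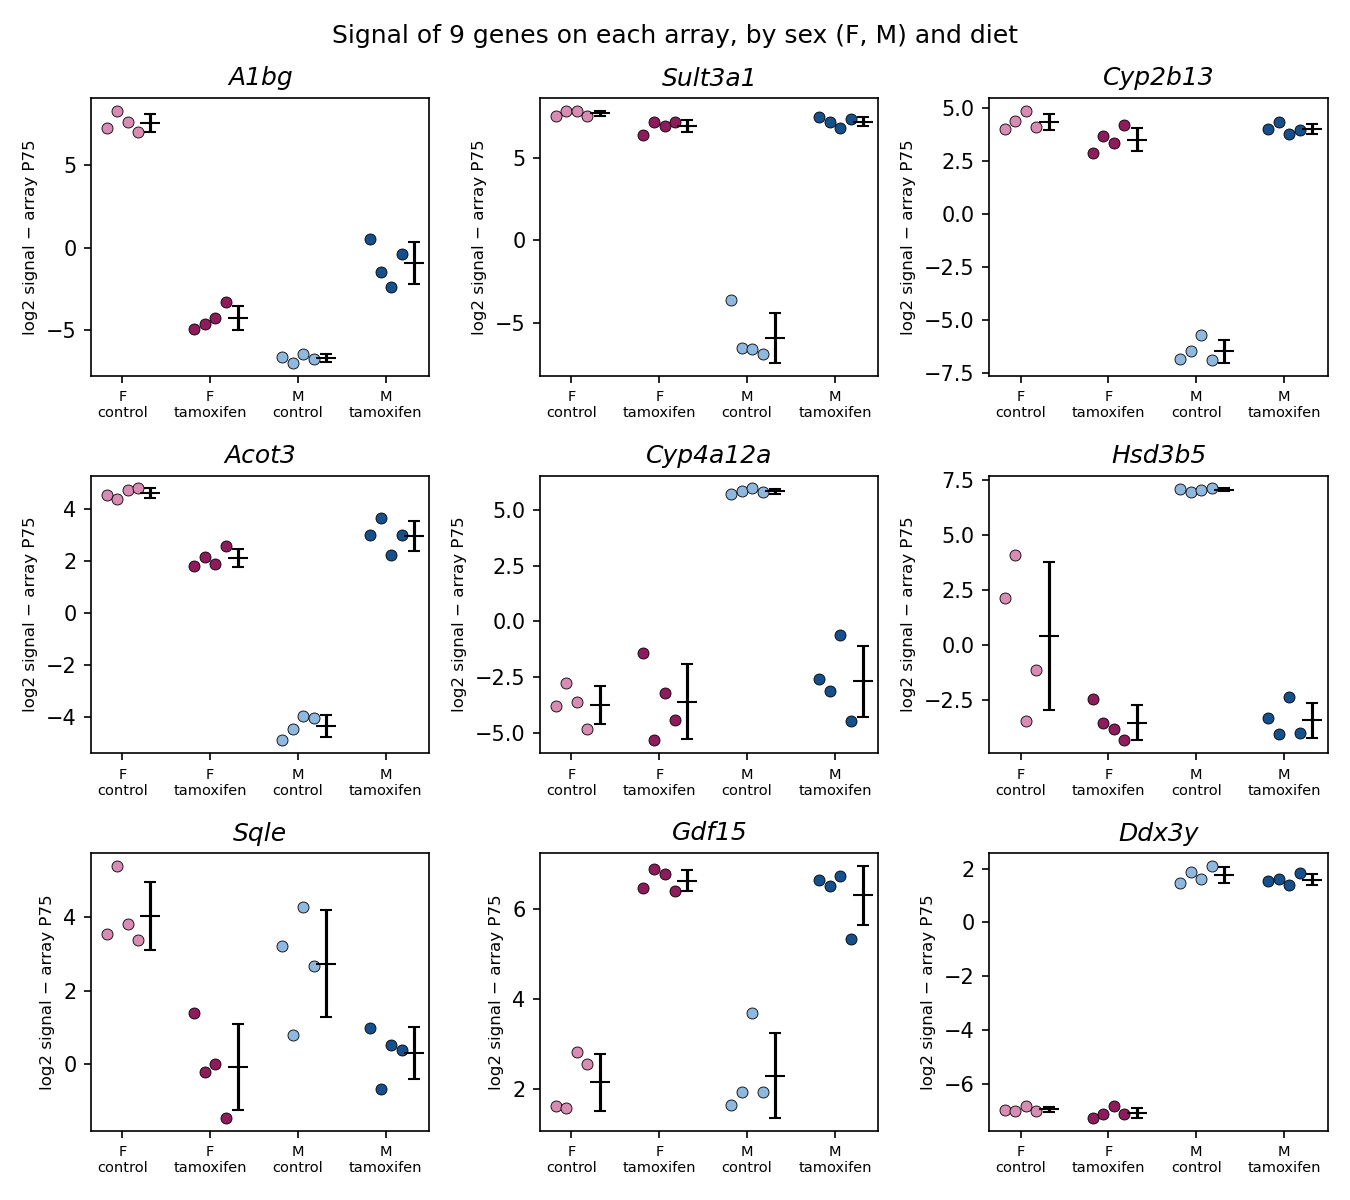
Log2 signal minus the array's 75th percentile for 9 genes on each array, with 1 point per mouse and the mean ± SD of the 4 mice per group. A1bg fell by 11.79 log2 units in females, Sult3a1, Cyp2b13 and Acot3 were higher in tamoxifen-fed than in control males, and the Y-linked Ddx3y separated the sexes on both diets.

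Lists tied to genotoxic and epigenetic effects held single large changes in females. Of 28 p53 targets and DNA damage genes 5 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.33): the stress cytokine Gdf15 rose by 4.49 ± 0.43 (adjusted p = 6.8e-06) and Cdkn1a, which encodes the cell cycle inhibitor p21, by 1.80 ± 0.39 (adjusted p = 0.0043). Of 42 DNA repair genes 2 rose and 3 fell (2 and 3 adjusted over the list alone), of 49 DNA methylation and chromatin genes 3 rose and 2 fell (2 and 2), and of 27 cell cycle genes 1 rose and 1 fell (1 and 0); none of these lists was called (adjusted p = 0.72, 0.60 and 0.83). The DNA methyltransferase Dnmt3b fell by 1.12 ± 0.18. Dnmt1, the maintenance methyltransferase, was higher by 0.29 ± 0.09 (adjusted p = 0.043), which was not past the threshold on leaving out any 1 of the 8 mice except female tamoxifen 4 (adjusted p = 0.053 to 0.11), nor with normexp (0.26). The repair enzyme Mgmt was lower, at -0.61 ± 0.18 (adjusted p = 0.025), a call lost without female control 2 or 3 or female tamoxifen 1 or 3 (adjusted p = 0.056 to 0.074) and with normexp (0.051). The proliferation marker Mki67 gave -0.25 ± 0.62 (adjusted p = 0.82).

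Of 33 xenobiotic targets of the nuclear receptors CAR and PXR 2 rose and 6 fell in females (2 and 6 adjusted over the list alone, camera adjusted p = 0.93), with Abcc3, a conjugate exporter, up by 1.48 ± 0.30. Cyp3a11 gave 0.61 ± 0.26 (adjusted p = 0.10), which passed without female tamoxifen 1 (0.85, adjusted p = 0.023), and Cyp2b10 gave 0.04 ± 0.40 (adjusted p = 0.96). Cyp1a2 gave -0.61 ± 0.25 (adjusted p = 0.095, 0.035 without female tamoxifen 4). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, gave -1.72 ± 0.59 (adjusted p = 0.049), and no longer passed when any 1 of the 8 mice was left out (adjusted p = 0.061 to 0.14). The oestrogen receptor gene Esr1 fell by 0.63 ± 0.17 (adjusted p = 0.014), and Lpin1, a phosphatidate phosphatase, gave 1.25 ± 0.67 (adjusted p = 0.20), and 1.93 (adjusted p = 0.029) without female control 3.

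The comparison of tamoxifen-fed with control males asked the same of the other sex. Sulfotransferases were among the genes that rose most in fitted values: Sult3a1 by 13.06 ± 0.52 (adjusted p = 1.5e-10), and Sult2a6, Sult2a1, Sult2a4 and Sult2a2 by 11.78 ± 0.48, 11.75 ± 0.59, 11.49 ± 0.54 and 11.41 ± 0.39. These Sult2a genes are close paralogs whose probes can bind one another's transcripts, so their values are not independent. Other kept probes of Sult2a6 gave 11.84 and 3.86 in males, so its size depends on the probe. Sult3a1 was above background on 1 male control array and the Sult2a genes on 2 or 3, so these sizes rest partly on arrays below background and are not ranked against the bounds that follow. Kcnt1 was at least 412-fold higher (adjusted p = 3.1e-10), the cytochrome P450 Cyp2b13 at least 417-fold (adjusted p = 7.0e-12) and Sult3a2 at least 321-fold, all 3 against male controls with no array well above background. The steroid dehydrogenase Hsd3b5 had the largest fitted fall, -10.49 ± 1.14 (adjusted p = 9.3e-06). Next came the fatty acid hydroxylases Cyp4a12b (-8.56 ± 0.86) and Cyp4a12a (-8.50 ± 0.79), themselves close paralogs. Nuggc (-8.19 ± 0.84), the fatty acid elongase Elovl3 (-7.92 ± 0.40) and the Wnt inhibitor Dkk4 (-7.55 ± 0.56) fell too. The protease Capn8 and the potassium channel Kcnk1 ended below background, at least 89.1-fold and 36.8-fold lower. In all, 2205 genes rose and 2307 fell, of which 878 and 402 changed at least 2-fold. On slide 1 alone 1292 genes passed and on slide 2 alone 1955; with the slide as a block 4578 passed, with normexp 2820 and with scaling to the array median 2992. The balance moved with the scaling, to 2050 higher and 942 lower with the array median and 2549 and 1649 with quantile normalization.

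Both sex-biased lists moved towards the other sex in treated males. Of 23 female-biased liver genes 22 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 5.62, and 5.64 and 5.20 on slides 1 and 2 (camera adjusted p = 1.2e-26); the median was 3.77 with members below background in male controls set to their bound, and 2.84 with normexp. This list also passed with an estimated correlation (adjusted p = 0.0024, 1 of 35 splits of the 8 male arrays). Sult3a1 and Sult2a1 led it. All 25 of the male-biased genes measured fell (25 adjusted over the list alone), with a median of -2.06, and -2.30 and -1.92 on the slides (adjusted p = 2.9e-18, adjusted p = 0.15 with an estimated correlation, 1 of 35 splits), led by Hsd3b5 and Cyp4a12b. Of 27 genes of oestrogen and growth hormone signalling 8 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.29, and 0.11 and 0.27 on the slides (adjusted p = 0.045, adjusted p = 0.34 with an estimated correlation, 6 of 35 splits, 0.076 with quantile normalization, median 0.19 with normexp). Its first members were Cux2, a female-specific repressor in liver, at least 3.67-fold higher, and Bcl6, a male-biased repressor, which fell by 2.08 ± 0.35. The Cux2 call was lost with normexp (0.54, adjusted p = 0.065). Esr1 gave 0.21 ± 0.17 (adjusted p = 0.35).

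Lists of fatty acid metabolism had more genes up than down in males. Of 36 genes of fatty acid oxidation and PPARalpha targets 20 rose and 3 fell (20 and 5 adjusted over the list alone), with a median of 0.39, and 0.38 and 0.35 on the slides (camera adjusted p = 1.0e-07, adjusted p = 0.59 with an estimated correlation, 1 of 35 splits). The fatty acid hydroxylase Cyp4a14 rose by 7.88 ± 0.84 and the acyl-CoA thioesterase Acot3 by 7.31 ± 0.27. Of 28 genes of fatty acid and triglyceride synthesis 9 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.20, and 0.34 and 0.15 on the slides (adjusted p = 0.038, adjusted p = 0.80 with an estimated correlation, 5 of 35 splits); Thrsp rose by 1.54 ± 0.33 and the elongase Elovl6 by 1.49 ± 0.21. In cholesterol synthesis 5 of 25 genes fell and 0 rose (4 and 0 adjusted over the list alone, median -0.34, -0.23 and -0.44 on the slides, adjusted p = 0.18). Sqle gave -2.43 ± 0.71 (adjusted p = 0.017). Sqle was not past the threshold without male control 3 or male tamoxifen 2 (adjusted p = 0.055 and 0.054).

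Of 28 acute phase and inflammation genes 14 fell and 2 rose in males (16 and 2 adjusted over the list alone), with a median of -0.42, and -0.55 and -0.21 on slides 1 and 2 (camera adjusted p = 0.024, adjusted p = 0.80 with an estimated correlation, 16 of 35 splits, 0.17 and median -0.22 with quantile normalization). The chemokine Cxcl1 fell by 3.88 ± 0.81 and the metallothionein Mt2 by 2.51 ± 0.64. Of 15 markers of fetal liver and preneoplasia 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.34, and 0.69 and 0.29 on the slides (adjusted p = 0.038, adjusted p = 0.59 with an estimated correlation, 7 of 35 splits, 0.11 with quantile normalization and with normexp, median 0.16 with normexp). Ly6d rose by 3.39 ± 0.45 and the steroid reductase Akr1c18 by 2.13 ± 0.34. In females 2 of these 15 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.40), and Tff3, a trefoil peptide, was at least 7.02-fold higher there, from below background on the 4 control arrays.

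Markers of 4 cell types other than hepatocytes were called higher in treated males, on the same arrays as the gene groups above, and lists of 6 further cell types were not called. Of 17 Kupffer cell and macrophage genes 13 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 1.76, and 1.83 and 1.57 on slides 1 and 2 (camera adjusted p = 2.0e-06, adjusted p = 0.59 with an estimated correlation, 3 of 35 splits). The Kupffer cell receptors Timd4 and Clec4f rose by 2.32 ± 0.41 and 1.89 ± 0.34. Of 19 endothelial genes 13 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.68, and 0.73 and 0.63 on the slides (adjusted p = 5.1e-07, adjusted p = 0.59 with an estimated correlation, 3 of 35 splits), led by Bmp2 (0.99 ± 0.15) and Gpr182 (0.98 ± 0.12). Of 17 stellate cell and fibroblast genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.49, and 0.70 and 0.33 on the slides (adjusted p = 0.011, adjusted p = 0.78 with an estimated correlation, 16 of 35 splits), among them collagen Col1a1 (1.42 ± 0.40) and desmin, Des (1.07 ± 0.20). Of 13 T and NK cell genes 8 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 1.60, or 1.11 with bounds, and 1.83 and 1.37 on the slides (adjusted p = 0.030, adjusted p = 0.78 with an estimated correlation, 1 of 35 splits). Granzyme Gzma rose by 3.098 ± 0.29 and Cd3g, of the T cell receptor complex, by 2.42 ± 0.43. This last list was not called with quantile normalization (adjusted p = 0.095) or normexp (0.21, median 0.35), and Cd3g was not called with normexp (0.59, adjusted p = 0.057). In females the Kupffer cell list had a median of 0.61, and 0.15 and 1.05 on slides 1 and 2, with 2 of 17 genes up and 0 down (2 and 0 adjusted over the list alone, adjusted p = 0.13). There the stellate cell list had a median of 0.18, and 0.14 and 0.15 on the slides, with 2 up and 2 down of 17 (2 and 2, adjusted p = 0.42). The T and NK cell list in females had a median of 0.20, and -0.11 and 0.51 on the slides, with 1 up and 1 down of 13 (1 and 1, adjusted p = 0.72).

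**Figure D3:**
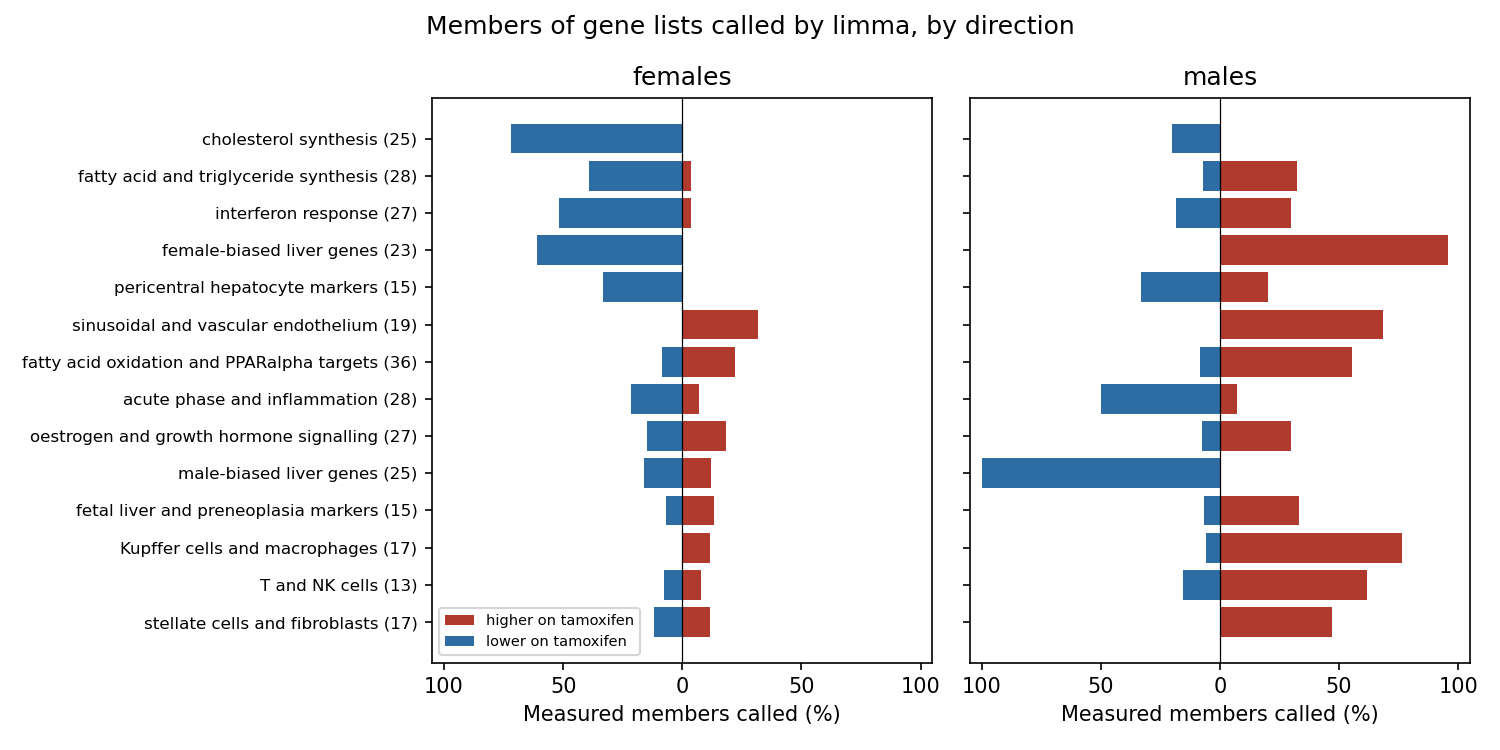
Percent of the measured members of each of 14 gene lists that were called higher (to the right) or lower (to the left) with tamoxifen, in females and in males. In males 22 of 23 female-biased genes rose and all 25 of the male-biased genes measured fell, while cholesterol synthesis had 18 of 25 genes lower in females.

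The list of CAR and PXR targets was mixed in males: of 33 genes 14 rose and 9 fell (15 and 9 adjusted over the list alone), the median was -0.03 and the mean 0.50 (camera adjusted p = 0.18, 0.025 with normexp). Cyp2b10 rose by 5.67 ± 0.40 (adjusted p = 9.9e-08), the organic anion transporter Slco1a4 by 3.29 ± 0.42 and Cyp3a11 by 1.93 ± 0.26 (adjusted p = 6.8e-05), and Cyp1a2 fell by 1.33 ± 0.25 (adjusted p = 0.0010). Cyp7a1 gave -1.34 ± 0.59 (adjusted p = 0.096, -2.01 and 0.0042 without male control 3) and Lpin1 0.91 ± 0.67 (adjusted p = 0.32). Of 28 p53 targets 6 rose and 4 fell (6 and 4 adjusted over the list alone, adjusted p = 0.75), with Gdf15 up by 4.01 ± 0.43 and Cdkn1a at -0.37 ± 0.39 (adjusted p = 0.49). Of 42 DNA repair genes 1 rose and 7 fell (0 and 5 adjusted over the list alone, adjusted p = 0.76), of 49 DNA methylation and chromatin genes 1 rose and 8 fell (1 and 8, adjusted p = 0.29). Of 27 cell cycle genes 1 rose and 5 fell (1 and 5, adjusted p = 0.50). The methyl-CpG binding protein Mbd1 fell by 1.41 ± 0.17 and Dnmt3b by 0.77 ± 0.18. Cyclin D1, Ccnd1, rose by 2.20 ± 0.37, and Dnmt1 and Mki67 gave 0.14 ± 0.09 (adjusted p = 0.29) and -0.51 ± 0.62 (adjusted p = 0.56).

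Whether the response differed between the sexes was tested as the male response minus the female response. A1bg had the largest fitted difference, 17.55 ± 0.72 (adjusted p = 5.6e-10): it fell in females, and in males it was at least 13.6-fold higher on tamoxifen. Sult3a1 (13.83 ± 0.73), Sult3a2 (11.93 ± 0.43) and Sult2a6 (11.81 ± 0.67) were also far higher in response in males. At the other end lay Cyp4a12b (-8.75 ± 1.22), Cyp4a12a (-8.65 ± 1.12), Elovl3 (-8.39 ± 0.57), Capn8 (-8.14 ± 0.38) and the acetyltransferase-like Nat8f5 (-8.02 ± 0.56). These are fitted values, and for A1bg, Sult3a1, Sult3a2, Sult2a6, Cyp4a12a, Capn8 and Nat8f5 they rest partly on arrays below background. The difference was positive for 1091 genes and negative for 1031. Of these 2122 genes, 1868 also differed between the sexes on the control diet. For 1867 of them the difference in response ran against that sex difference. The control arrays enter both values, so this is partly built in. On slide 1 alone 273 genes passed and on slide 2 alone 257, 2230 with the slide as a block, 1243 with normexp and 1195 with the array median. The balance was 806 positive to 389 negative with the array median and 1230 to 926 with quantile normalization.

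Gene lists also differed in response between the sexes. Among 23 female-biased genes 22 had a higher response in males and 0 a lower one (22 and 0 adjusted over the list alone), with a median difference of 7.70, and 8.19 and 8.27 on slides 1 and 2 (camera adjusted p = 3.4e-40, adjusted p = 0.00033 with an estimated correlation, 1 of 100 splits). Among 25 male-biased genes 21 had a lower and 0 a higher response in males (22 and 0 adjusted over the list alone, median -2.84, and -3.40 and -2.56 on the slides, adjusted p = 1.6e-19, adjusted p = 0.12 with an estimated correlation, 3 of 100 splits). The response in males was higher for 10 of 27 interferon genes (15 adjusted over the list alone, median 0.66, and 0.94 and 0.42 on the slides, adjusted p = 2.2e-07) and for 10 of 28 genes of fatty acid and triglyceride synthesis (13 adjusted over the list alone, median 0.51, and 0.68 and 0.38 on the slides, adjusted p = 1.1e-05). It was also higher for 6 of 25 of cholesterol synthesis (7 adjusted over the list alone, median 0.85, and 1.25 and 0.57 on the slides, adjusted p = 1.1e-05). No gene of these 3 lists had a lower response in males. Adjusted p = 0.33, 0.33 and 0.71 with an estimated correlation, in that order, and 2, 4 and 30 of 100 splits gave as small a p. On the control diet 9, 14 and 8 genes of these lists were higher in females, and 0, 1 and 0 lower. The median female minus male differences were 0.36, 0.46 and 0.69 there, and -0.32, -0.20 and -0.18 on tamoxifen. The control arrays enter both the sex difference and the difference in response, so these values are not independent. For fatty acid oxidation and PPARalpha targets 10 of 36 genes responded higher and 2 lower in males (10 and 3 adjusted over the list alone, median 0.29, and 0.20 and 0.33 on the slides, adjusted p = 6.0e-06, adjusted p = 0.67 with an estimated correlation, 7 of 100 splits). For the Kupffer cell list it was 1 of 17 higher and 0 lower (8 and 1 adjusted over the list alone, median 1.13, and 1.69 and 0.56 on the slides, adjusted p = 0.0032, adjusted p = 0.71 with an estimated correlation, 32 of 100 splits, median 0.71 with normexp). Of 22 genes of ER stress and amino acid response 5 responded lower and 0 higher in males (5 and 0 adjusted over the list alone, median -0.51, and -0.65 and -0.35 on the slides, adjusted p = 0.010, adjusted p = 0.63 with an estimated correlation, 11 of 100 splits, median -0.33 with quantile normalization), with asparagine synthetase Asns at -3.19 ± 0.38.

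Changes shared by the sexes were counted as overlap, and no test was made of it. The group means compared have no array in common, but both comparisons use the same estimate of each gene's spread. The calls in females and in males are therefore not fully independent. Of the genes called, 601 rose in both sexes where independent lists would share 213, and 589 fell in both where 280 would be shared. Opposite changes were fewer than that: 100 genes rose in females and fell in males, against 223, and 145 the reverse, against 267. Across genes, which are not independent replicates, the responses had Pearson's r = 0.35 and Spearman's rho = 0.28. Pemt, which makes phosphatidylcholine, fell by 2.24 ± 0.11 in each sex, the periportal cytochrome P450 Cyp2f2 by 3.35 ± 0.20 in females and 4.01 ± 0.20 in males, and the keratin Krt23 rose by 3.52 ± 0.39 and 5.604 ± 0.39. Kcnt1, Obp2a, Syn2, Igfbpl1 and Sohlh1 were below background in controls of both sexes and above it in treated mice of both; in males they were at least 412, 130, 221, 15.1 and 8.87-fold higher.

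The control mice gave the sex difference against which these responses stand, and checked the sex labels. The Y-linked Eif2s3y, Ddx3y and Uty were at least 193, 103 and 6.67-fold higher in males, with no female control array above background, and Xist, the transcript of the inactive X chromosome, was higher in females by 4.76 ± 0.91 (adjusted p = 0.0014). The Xist probe was above background on 2 of the 4 male control arrays, numbers 1 and 3, at 16.1% and 18.99% of the female control level. Among other genes A1bg was at least 4738-fold higher in females, and Sult3a1, Sult2a1, Sult2a6 and Sult2a4 were higher by 13.56 ± 0.52, 11.85 ± 0.59, 11.71 ± 0.48 and 11.49 ± 0.54. Cyp4a12b, Cyp4a12a and Nat8f5 were higher in males, with differences of -9.99 ± 0.86, -9.56 ± 0.79 and -8.74 ± 0.40 as female minus male. In all, 1985 genes were higher in females and 2539 in males, of which 550 and 385 differed at least 2-fold. On slide 1 alone 821 genes passed and on slide 2 alone 1559, 4592 with the slide as a block and 2684 with the array median. More genes were higher in females than in males with quantile normalization (2312 and 1846) and with the array median (1364 and 1320). Without male controls 1 and 3, an alternative chosen after the data were seen, 2468 passed here, 1272 for the difference in response and 3065 for the response in males.

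To follow sex-biased genes without choosing and measuring them on the same controls, genes that differed at least 2-fold between control females and males on 1 slide were measured on the other. The 365 and 378 female-biased genes so chosen on slides 1 and 2 had a median female minus male difference of 1.31 and 1.49 on the control diet and of -0.04 and -0.12 on tamoxifen. Their median response was 1.13 and 1.32 in males and -0.24 and -0.28 in females. The 263 and 311 male-biased genes had a median difference of -1.37 and -1.45 on the control diet and of -0.11 and -0.02 on tamoxifen, with a median response of -1.01 and -1.28 in males and 0.26 and 0.10 in females. The sexes on the tamoxifen diet were compared directly after these data were seen: 97 genes were higher in females and 140 in males, 74 of them at least 2-fold. Of these 237 genes 83 differed in the same direction on the control diet and 54 in the opposite one. A1bg was opposite, higher in females on the control diet and at -3.35 ± 0.51 on tamoxifen. The count was 290 with the slide as a block, 7 and 5 on slides 1 and 2 alone, and 83 with the array median.

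**Figure D4:**
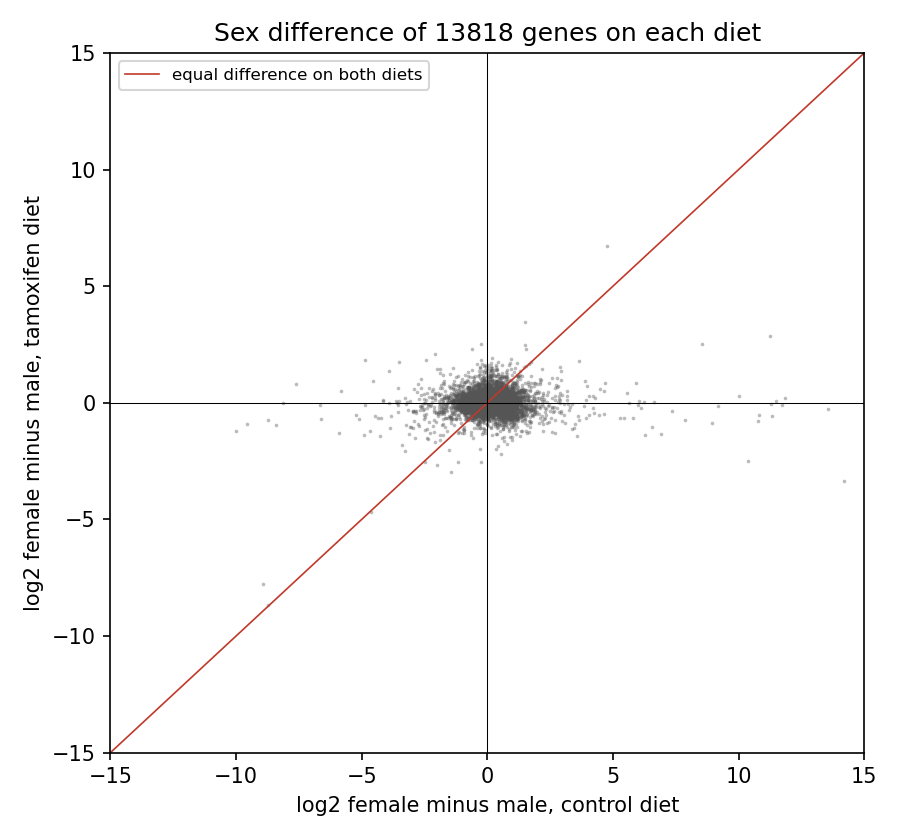
Female minus male log2 difference of each of 13818 genes on the control diet (horizontal axis) and on the tamoxifen diet (vertical axis), 1 point per gene, with the line of equality in red. On the control diet 4524 genes differed by the test, and on the tamoxifen diet 237.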

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

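The tests of mislabelled mice, of selection on shared controls, of array scaling between the sexes, of a smaller hepatocyte share and of scaling for the T and NK cell list were chosen after the results were seen.

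A test of the difference in response between the sexes called 52 of 89 named genes and 8 gene lists. For 1 of the 52, Obp2a, both responses are bounds, so its difference has no exact size and is not shown to differ. As male minus female response in log2, the genes Sult3a1, Sult3a2, Sult2a6, Sult2a1, Sult2a4, Sult2a2 and Cyp2b13 had 13.83, 11.93, 11.81, 11.65, 11.42, 11.35 and 11.34, and A1bg had 17.55. Other positive differences were those of Acot3 (9.82), Hao2 (8.42), Cyp4a14 (8.22), Cux2 (7.60), Prom1 (6.33), Hsd3b1 (6.01), Cyp2b10 (5.62), G0s2 (2.95), Cyp2c37 (2.90), Akr1c18 (2.68), Slco1a4 (2.59), Acacb (2.48), Fmo2 (2.37), Elovl6 (2.11), Pklr (1.94), Thrsp (1.70) and Cyp3a11 (1.32). Ly6d (3.43), Ccnd1 (2.37), Krt23 (2.08), Cxcl10 (1.98), Cd3g (1.88), Ifit1 (1.54), Gbp3 (1.53), Mgmt (0.86) and Esr1 (0.84) were positive too. Negative differences were those of Cyp4a12b (-8.75), Cyp4a12a (-8.65), Elovl3 (-8.39), Capn8 (-8.14), Nat8f5 (-8.02), Dkk4 (-7.46), Hsd3b5 (-6.54), Kcnk1 (-6.34), Tff3 (-4.42), Bcl6 (-4.31), Gstp1 (-4.26), Nuggc (-3.73), Pfkfb3 (-3.65), Asns (-3.19), Cdkn1a (-2.17), Mbd1 (-1.74), Obp2a (-1.71) and Usp2 (-1.70). Among lists the median differences were 7.70 for female-biased genes, 1.13 for Kupffer cells, 0.85 for cholesterol synthesis, 0.66 for interferon response, 0.51 for fatty acid and triglyceride synthesis, 0.29 for fatty acid oxidation, -0.51 for ER stress and -2.84 for male-biased genes. With an estimated correlation 2 of the 25 list calls remain, those of the female-biased list in males and for the difference, and 41 of 100 splits of the mice called as many lists for the difference. The gene values are fitted, and those of A1bg, Acot3, Capn8, Cd3g, Cux2, Cyp2b13, Cyp4a12a, Dkk4, Hao2, Hsd3b1, Kcnk1, Ly6d, Nat8f5, Nuggc, Sult2a1, Sult2a2, Sult2a4, Sult2a6, Sult3a1, Sult3a2 and Tff3 rest partly on arrays below background.

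Fewer genes differed between the sexes on tamoxifen (237) than on the control diet (4524). Mislabelled treated mice are argued against by Ddx3y, above background on the 4 treated male arrays and on no treated female array and at least 102-fold higher in males, while the gap of 4.16 log2 units for Uty was taken against signal below background and is no bound. For genes chosen on 1 slide, the median sex difference on the other slide was compared between the diets. On tamoxifen it was at most 7.97% of that on the control diet, so selection on shared control arrays does not explain the loss. Over 4 scalings the count on tamoxifen was at most 6.05% of that on the control diet, which argues against array scaling. Tamoxifen may move sex-biased transcripts of male liver towards the female level, a hypothesis found and tested on the same mice. The checks above do not bear on that direction, and treated females changed too. There 14 of 23 female-biased list genes fell and 0 rose (median -0.88). Female-biased genes chosen on 1 slide had median responses of -0.24 and -0.28 in females, and male-biased ones 0.26 and 0.10. A change in hormones or in feeding was not measured.

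Markers of several cell types other than hepatocytes rose together in tamoxifen-fed males, but none of these list calls held with an estimated correlation. A smaller share of hepatocyte RNA would raise alike those markers that are absent from hepatocytes and clear of background. The mean rise of the Kupffer cell list exceeded that of the endothelium list by 0.70 log2 units (SE 0.15). Markers with hepatocyte or background signal would rise less, so this difference does not decide whether the share fell. Array scaling is argued against for the Kupffer cell list, whose lowest median over 3 alternatives was 1.46, and cannot be told apart for the T and NK cell list, whose median was 0.35 with normexp. Loss of a sex difference cannot be told apart from a rise of its own. For the Kupffer cell list control females exceeded control males by a median of 0.71, 1.29 on slide 1 and 0.05 on slide 2. On tamoxifen that difference was -0.42. Of 19 endothelial genes 13 were higher in control females and 0 lower, with a median of 0.57, and 0.65 and 0.45 on the slides. On tamoxifen 0 were called and the median was 0.27. For T and NK cells 8 of 13 genes were higher in control females and 1 lower, and for stellate cells 6 of 17 and 0. Their medians were 0.97 and 0.44 on the control diet, and -0.16 and 0.09 on tamoxifen. The male control arrays enter each of these values except the differences on tamoxifen. More of these cells, more RNA per cell, or both could underlie the rise.

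Single arrays stood apart from the other 3 of their group in 18 groups of values, 0.947 per 20 tested, and chance gives about 1 in 20. As the log2 difference from the mean of the other 3 arrays, in female controls these were Dkk4 (2.05), Ly6d (1.76) and Esr1 (-0.62) in mouse 1, Igfbpl1 (1.69), Hao2 (0.81) and Acacb (0.44) in mouse 2 and Cyp7a1 (1.35) in mouse 4. In tamoxifen-fed females it was Bcl6 (-1.29) in mouse 3. In male controls they were Sult3a1 (3.03), Sult2a2 (2.05) and Dkk4 (1.60) in mouse 1, Igfbpl1 (1.84) in mouse 2, and Gdf15 (1.87) and Pfkfb3 (-1.34) in mouse 3. In tamoxifen-fed males they were Psat1 (-1.11) in mouse 2, Igfbpl1 (-0.39) in mouse 3 and Gdf15 (-1.30) in mouse 4, and mouse 1 had the highest 75th percentile of signal, 408 units. Dkk4 in female controls and Igfbpl1 in controls of both sexes were below background on each array, and Sult3a1 and Sult2a2 on part of the male control arrays, so these differences are not shown to be more than background signal.

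Probes without a gene symbol enter none of the comparisons of genes. Among them 23 probes in females and 54 in males were well above background on the 4 tamoxifen arrays of that sex and on none of its control arrays.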

How the results depend on the processing

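Leaving out male controls 1 and 3 was an alternative chosen after the data were seen, and the others were planned. The cause of a difference was not tested except where fewer arrays or a stricter threshold gives it.

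Of 1680 values of named genes with 1 mouse left out, 1556 kept their direction and side of the threshold, 73 fell short of the threshold, 11 passed it and 40 moved. A value moved when its sign changed and it was called neither in the main fit nor in the alternative. Over mice left out the count of genes was 2127 to 2912 in females (3011 with all mice), 3657 to 4297 in males (4512), 1534 to 2249 for the difference in response (2122) and 3310 to 4297 for the sexes on the control diet (4524). Of 400 values on 1 slide alone, 298 stayed, 76 fell short, 3 passed and 23 moved. Of 2619 values under other alternatives, 2527 stayed, 61 fell short, 15 passed, 14 moved and 2 reversed.

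Slides 1 and 2 alone, with 2 mice per group, gave 420 and 1140 genes in females, 1292 and 1955 in males, 273 and 257 for the difference and 821 and 1559 for the sexes on the control diet. Scaling to the array median gave 1618, 2992, 1195 and 2684 genes. Normexp gave 2820 genes in males and 1243 for the difference. Without male controls 1 and 3 the difference gave 1272 and the sexes on the control diet 2468. A change of at least 2-fold left 638, 1280, 873 and 935 genes, and adjusted p under 0.01 left 1566, 2678, 917 and 2445. With the slide as a block the counts were 3085, 4578, 2230 and 4592, and with the replicate block 3042, 4524, 2159 and 4467.

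Of 108 list tests 25 passed, 2 with an estimated correlation and 42 with fry, which asks a different question; quantile normalization gave 21, normexp 24. Kdr reversed with normexp, to -0.0899 in females (adjusted p = 0.687) and -0.0902 in males (0.686). The probe was chosen anew there, and the second Kdr probe gave -0.12 in females and -0.21 in males in the main values. A change of probe and an effect of the background correction cannot be told apart here. Without a minimum fold change for choosing sex-biased genes, the response of female-biased genes was 0.81 in males against 1.23 and -0.18 in females against -0.26, and that of male-biased genes in males was -0.67 against -1.15. Signal over background limits genes below background in 1 group to a bound on their fold: 53 of the called genes in females, 153 in males and 116 between the sexes.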

Other observations

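The tests of the Xist signal were chosen after it was seen, and the splits of the mice were planned.

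The remaining gene lists were not called in the contrasts given here. In females and males, in that order, camera's adjusted p was 0.16 and 0.75 for AhR targets, 0.42 and 0.75 for NRF2 targets, 0.095 and 0.82 for phase II conjugation and 0.20 and 0.75 for one-carbon metabolism. Of 9 AhR targets 0 rose and 3 fell in females (0 and 5 adjusted over the list alone) and 2 rose and 1 fell in males (2 and 1). Of 28 NRF2 targets 3 rose and 2 fell in females (3 and 2) and 8 rose and 10 fell in males (9 and 10), and Gstp1 rose by 1.26 ± 0.14 in females and fell by 3.00 ± 0.14 in males. Of 28 phase II genes 3 rose and 8 fell in females (4 and 10) and 10 rose and 11 fell in males (10 and 11). Of 28 one-carbon genes 2 rose and 6 fell in females (2 and 8) and 5 rose and 5 fell in males (5 and 5).

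Among lists of lipid, bile acid and glucose metabolism, of 20 genes of lipid droplets and export 3 rose and 4 fell in females (4 and 7 adjusted over the list alone, adjusted p = 0.21) and 1 rose and 4 fell in males (0 and 4, adjusted p = 0.86). G0s2 fell by 1.95 ± 0.36 in males. Of 28 bile acid genes 4 rose and 5 fell (4 and 5, adjusted p = 0.83) and 7 rose and 7 fell (8 and 9, adjusted p = 0.86). Of 22 genes of glucose metabolism 4 rose and 3 fell (4 and 4, adjusted p = 0.97) and 0 rose and 3 fell (0 and 3, adjusted p = 0.75), and Pfkfb3 rose by 2.03 ± 0.45 in females and fell by 1.62 ± 0.45 in males. In females 8 of 36 genes of fatty acid oxidation rose and 3 fell (8 and 3, adjusted p = 0.62).

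Of 17 clock genes 2 rose and 1 fell in females (2 and 1 adjusted over the list alone, adjusted p = 0.89) and 0 rose and 3 fell in males (0 and 2, adjusted p = 0.43), with Usp2 up by 2.16 ± 0.36 in females. Of 22 ER stress genes 3 rose and 2 fell in females (3 and 2, adjusted p = 0.40) and 1 rose and 8 fell in males (1 and 9, adjusted p = 0.057). In females 2 of 28 acute phase genes rose and 6 fell (2 and 6, adjusted p = 0.52), and 5 of 27 genes of oestrogen and growth hormone signalling rose and 4 fell (5 and 4, adjusted p = 0.98). In males 8 of 27 interferon genes rose and 5 fell (8 and 5, adjusted p = 0.43).

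Of 15 pericentral genes 3 rose and 5 fell in males (4 and 7 adjusted over the list alone, adjusted p = 0.75). Of 15 periportal genes 1 rose and 4 fell in females (1 and 5, adjusted p = 0.14) and 2 rose and 3 fell in males (2 and 3, adjusted p = 0.69). For females and males, B and plasma cells had 1 up and 0 down of 5 genes (1 and 0, adjusted p = 0.59) and 3 up and 1 down (3 and 1, adjusted p = 0.30). Neutrophils had 0 up and 2 down of 4 (0 and 2, adjusted p = 0.32) and 0 up and 1 down (0 and 1, adjusted p = 0.37). Cholangiocytes had 2 up and 0 down of 14 (2 and 0, adjusted p = 0.83) and 2 up and 1 down (2 and 1, adjusted p = 0.26). Erythroid cells had 0 up and 0 down of 8 genes (0 and 0, adjusted p = 0.40) and 0 up and 1 down (0 and 1, adjusted p = 0.76). Adipocytes had 0 up and 1 down of 5 (0 and 1, adjusted p = 0.72) and 1 up and 2 down (1 and 2, adjusted p = 0.60). Exocrine pancreas had 0 up and 1 down of 6 (0 and 2, adjusted p = 0.28) and 0 up and 2 down (0 and 2, adjusted p = 0.69). Sex chromosome transcripts had 1 up and 0 down of 4 in females (1 and 0, adjusted p = 0.90), Eif2s3y near background, and 0 of 4 in males (adjusted p = 0.69).

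The median, the mean and the direction of the test differed in sign for some lists, none of them called. These were CAR and PXR targets, glucose metabolism, male-biased genes, clock genes, cholangiocytes, adipocytes and sex chromosome transcripts in females. In males they were CAR and PXR targets, phase II, bile acid, one-carbon, interferon, erythroid cells and adipocytes, and for the difference DNA repair and exocrine pancreas.

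The Xist probe gave signal on male control arrays 1 and 3, at 16.1% and 18.99% of the female control level. RNA of a female mouse would bring its other transcripts, but 36 transcripts much higher in females had a median share of at most 0.0094%, which argues against it. A second Xist probe gave at most 1.36% and was not above background on these arrays; a signal of 1 probe only cannot be told apart from Xist RNA, since the level that the second probe would need lies near its limit of detection. No biological explanation was tested.

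The real grouping called more genes than any other split of the same mice. Each other split mixes the groups compared. The response then enters the spread and lowers the count, so these splits set no level expected by chance. With 35 splits, 1 of 35 is also the lowest share possible. The real split gave 3011 genes in females against at most 25 in the other splits, 4512 against 1 in males and 4524 against 6 for the sexes on the control diet, each the 1 of 35 splits with as many. For the difference in response the real count was 2122, 1 of 100 splits gave as many, and the highest other was 1613. Those splits relabelled mice within each sex, which is no model of equal responses in both sexes. Chance cannot be excluded for the number of lists called: 28 of 35 splits gave as many as the 6 in females (highest other 22), 4 of 35 as many as the 11 in males (highest other 11), and 41 of 100 as many as the 8 for the difference (highest other 15). For lists too these splits set no level expected by chance, since some keep part of the response. The highest other split in males differed from the real grouping in 2 arrays.

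Probes without a gene symbol were tested apart from genes. Of 10563 such probes, 366 were higher and 557 lower with tamoxifen in females, and 642 higher and 1713 lower in males.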
